A study of Mus musculus with 9 samples.

How the data were processed

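RNA was measured in 9 samples of mouse LSK cells on Agilent SurePrint G3 mouse arrays with 1 colour, Cy3. Per the labels' protocols, cells were sorted after transplantation, and cDNA was amplified from 3.67 ng of total RNA with an amplification kit for small inputs. The labels name 3 groups of 3 samples: empty vector, wild-type DNMT3A and DNMT3A R882H. The scans were quantified with Agilent Feature Extraction 10.10.1.1 on array design 028005, per the file headers, with probe coordinates on mouse build mm9. The intensity the authors deposited for each spot was background-subtracted and spatially detrended by that software, per the file headers, and lay on a linear scale beside the median pixel intensity and the local background. Each spot also had calls for being well above background, saturated or an outlier, per the file headers. The authors' deposited value table held log2 values for 41854 non-control probes. How it was made is not given in the sources used here. Setting its columns against the arrays showed log2 processed intensity minus the array's 75th percentile minus each probe's median over the 9 columns. Column medians were 0.0000 except for 1 of -0.0021. Of its 9 columns, 2 held the values of the array of the sample they were named for and 7 those of another sample, 4 of them of another group, so the scanner values were used and the table served as an alternative. The groups of all values given here rest on the labels of the scanner output.

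Each array had 62976 spots, of which 59305 were not controls and covered 55681 probes. No spot was saturated, and 154 to 184 spots per array had an outlier flag and were left out. The median pixel signal was 79 to 88 against a local background of 24 to 29. Processed intensities were taken to log2, the 75th percentile of the array was subtracted, and spots of a probe were averaged. A symbol was found for 27235 probes through their RefSeq accessions and a gene table, no probe had several, and 28446 probes had none and were tested apart from the genes. Symbols were updated for 4 list members. Probes well above background on all 3 arrays of at least 1 group numbered 31242, of which 17033 had a symbol. For each symbol the probe with the highest mean was kept, which gave 13120 genes, 3267 of them with 2 or more detected probes. Where such probes disagreed in sign for a named gene, their number is given.

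Differences between groups were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on all 9 arrays, which share 1 estimate of the spread with 6 residual and 2.82 prior degrees of freedom. Benjamini-Hochberg adjusted p-values under 0.05 were called. The median SE of a log2 fold change between R882H and empty vector was 0.232. A gene not well above background on any array of a group has only a bound there. Its fold is given as "at least", the brighter group's mean over the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own.

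Before the data were examined, 26 gene lists, the tests, the rule for named genes and most of the alternative settings were fixed. The lists covered stem and progenitor classes, blood lineages, endothelial and stromal cells, cell cycle and growth, epigenetic regulators, imprinted and germline genes, interferon and stress responses, and sex-linked genes. The 25 lists with at least 5 measured genes were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance 1 way without setting them against other genes, were run beside it. List medians were placed among 10000 random lists matched on mean signal in 20 bins, a test chosen after seeing the data. With genes that have only a bound set at it, the median of the interferon list against empty vector was 0.49 with R882H and 0.23 with wild-type DNMT3A, and no other list median moved by more than 0.00464. Named genes were, per comparison, the 8 largest changes in each direction among genes that passed and whose groups did not overlap. In a direction with fewer, the genes with the smallest p filled it up to 5 and are said not to have passed. To these were added the 4 members of smallest p of each called list and a fixed panel of 15 genes. RIKEN clones and gene models were left out of the names, and some genes that the rule names are not reported here.

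Replicate numbers in the labels were checked for pairing by correlating same-numbered deviations from the group means. Between wild-type DNMT3A and empty vector these were 0.116, 0.223 and 0.326, all above the 0.1 set as the limit. The numbers were therefore taken to pair these samples, from the data and not from any statement in the labels. The main tests did not use this pairing, and replicate number as a block was run as an alternative. Of these 6 arrays 5 correlated best with the array of their own number, while wild-type replicate 1 correlated at 0.191 with empty vector replicate 2. The arrays lay on 3 slides. Slide 1 held the 3 empty vector arrays and wild-type replicate 1, slide 2 held wild-type replicates 2 and 3 and R882H replicates 1 and 2, and slide 3 held R882H replicate 3. Slide was used as a block, and comparisons were repeated within slides.

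The tests were checked on simulated data with 200 of 13115 genes changed. For R882H against empty vector 43% of changes of 1 log2 unit and 86% of changes of 2 were recovered, with 8 false calls. For R882H against wild-type DNMT3A the shares were 33% and 86% with 5 false calls, and for wild-type DNMT3A against empty vector 41% and 75% with 6. A list shifted by 0.5 was called in each. For R882H against empty vector 1 list that had not been shifted was called too, against 0 in the other comparisons. Genes were simulated as independent, while the correlation estimated in the data was 0.31 for the stem cell list and 0.53 for the Myc list. The simulation therefore does not show how often camera wrongly calls a list of correlated genes.

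Alternatives fixed in advance were normexp background correction with an offset of 50, quantile normalization, the array median in place of the 75th percentile, the authors' value table, no filter or a filter on all 9 arrays, every probe on its own, outlier spots kept, an intensity trend with robust spread, array weights, only the 2 groups compared, replicate number or slide as a block, and each array left out in turn. Normexp used the median pixel signal, since the scanner output held no mean signal. Added after seeing the data were cyclic loess, the value table with columns given to the arrays whose values they held, replicate number 3 left out of all groups, slides 1 and 2 alone, and a simulation of the shared empty vector arrays with same-numbered arrays correlated. Where the array median was used, the median of all genes shifted to -0.18 in R882H against empty vector and to -0.11 against wild-type DNMT3A, each list median shifted with it, and camera tests lists relative to the other genes.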

Results

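Gene expression was measured in mouse LSK cells, the bone marrow fraction that lacks lineage markers and carries Sca-1 and Kit and that holds haematopoietic stem cells and multipotent progenitors. The cells had been transduced with GFP-labelled empty vector, with wild-type DNMT3A or with DNMT3A R882H, transplanted into C57BL/6 mice and sorted again. DNMT3A is a DNA methyltransferase that places new methyl groups on cytosines, and R882H is its recurrent substitution in acute myeloid leukaemia. Each of the 3 groups had 3 arrays, hybridised from cDNA amplified out of 3.67 ng of total RNA. Of 55681 probes per array, 56.2% ± 2.39 (SD, n = 3) were well above background with empty vector, 59.4% ± 4.72 (SD, n = 3) with wild-type DNMT3A and 60.8% ± 3.66 (SD, n = 3) with R882H. The 13120 named genes well above background on all arrays of at least 1 group were tested, and the number of arrays limits the precision. Nothing in the labels says that replicates of a group came from separate animals or cultures. The limma p-values of genes therefore measure the spread between these samples, which may be technical. Camera p-values of lists, at the preset correlation of 0.01, mostly measure the spread between genes, which are taken as almost independent.

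The transduced gene was examined first. The Dnmt3a probe named on the array read 1.07 ± 0.47 with empty vector, 1.26 ± 0.70 with wild-type DNMT3A and 1.43 ± 0.30 with R882H (log2 signal relative to the array's 75th percentile, SD, n = 3). The R882H mean lay 0.36 ± 0.37 (SE) log2 units from that of empty vector, with a limma adjusted p of 0.733. This difference was 0.10 without empty vector replicate 3, 0.56 without empty vector replicate 2, 0.22 without R882H replicate 1 and 0.80 with slide as a block. Those of R882H from wild-type DNMT3A and of wild-type DNMT3A from empty vector, 0.17 and 0.18, changed sign without 1 array. The first was -0.21 without wild-type replicate 3, and the second -0.11 without wild-type replicate 2 and -0.07 without empty vector replicate 3. Where this mouse probe lies relative to the transgene is not given in the sources used here, so its level does not test the labels. Dnmt1, the maintenance methyltransferase, and Dnmt3b, the other de novo methyltransferase, differed between R882H and empty vector by -0.15 ± 0.15 and 0.05 ± 0.31 log2 units. For Dnmt3b, 2 of 3 detected probes had the opposite sign. Across 17 measured genes of the DNA methylation machinery the median difference between these groups was -0.15, with an adjusted p of 0.334 by camera, a test of whether a list's genes shift relative to all others. The median was 0.0042 without empty vector replicate 1 and 0.04 with slide as a block.

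The comparison of R882H with empty vector asks how LSK cells carrying the mutant enzyme differ from cells carrying the vector alone. Genes typical of haematopoietic stem cells rose as a list: 25 of 27 measured members were higher with R882H. Their median log2 fold change was 0.69 (1.62-fold), with a camera adjusted p of 7.4e-06 (adjusted p = 0.396 with an estimated correlation). Members with the smallest p were Robo4, an endothelial and stem cell guidance receptor, at 1.21 ± 0.34 (SE), Gata2, a transcription factor needed for stem cell maintenance, at 0.62 ± 0.24, Krt18 at 0.60 ± 0.22 and the adhesion molecule Esam at 1.11 ± 0.46. Genes of the megakaryocyte lineage, which makes platelets, rose with a median of 0.70, 14 of 15 members being higher (adjusted p = 7.4e-06, and adjusted p = 0.306 with an estimated correlation). Among them the platelet adhesion receptor genes Itgb3, Gp1ba, Itga2b and Gp5 differed by 0.86 ± 0.17, 1.84 ± 0.43, 0.70 ± 0.25 and 2.10 ± 0.75 log2 units. In the other direction, genes of granulocyte and monocyte differentiation fell with a median of -0.47, and 21 of 26 members were lower (adjusted p = 0.00518, and adjusted p = 0.457 with an estimated correlation). They included Spi1, which encodes the myeloid transcription factor PU.1, at -0.75 ± 0.24, the azurophil granule genes Mpo and Ctsg at -0.90 ± 0.40 and -1.33 ± 0.62. Klf5 of the same list stood on the higher side at 1.35 ± 0.56. Cebpa, a driver of granulocyte commitment, stood at -0.47 ± 0.35 and Gata1, the master regulator of red cell and megakaryocyte genes, at 1.15 ± 0.38.

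These stem cell, megakaryocyte and granulocyte-monocyte lists also moved with the replicate number. Replicate 3 scored lowest of its group on the stem cell list in every group, at -0.88 with empty vector, -0.91 with wild-type DNMT3A and 0.19 with R882H, where the other 6 arrays lay between -0.15 and 0.78. Its granulocyte-monocyte score was the highest of its group, at 0.84, 0.68 and 0.17 in that order, and its megakaryocyte score the lowest, at -0.77, -0.68 and 0.19. R882H and empty vector arrays overlapped on 2 of these lists. Empty vector replicate 2 scored 0.29 on the stem cell list, above R882H replicate 3, and -0.36 on the granulocyte-monocyte list, below it. On the megakaryocyte list all empty vector arrays lay at -0.02 or below and did not overlap with R882H. On the first principal component, which held 29.6% of the variance, empty vector replicate 3 and wild-type replicate 3 lay at -53.0 and -33.9 and the other 7 arrays at -8.41 or above. Without empty vector replicate 3 the stem cell median was 0.27 (adjusted p = 0.0109), and without empty vector replicate 2 it was 1.06. The granulocyte-monocyte list was no longer called without empty vector replicate 3, at -0.42 (adjusted p = 0.185), while its median was -0.73 without either empty vector replicate 2 or R882H replicate 3 and -0.30 without R882H replicate 2. Without number 3 in any group, a setting chosen after seeing the data, the stem cell median was 0.39 with the call kept, and the Hox (0.31, adjusted p = 0.0529), interferon (0.32, adjusted p = 0.0576) and immediate early (0.13, adjusted p = 0.439) lists were not called.

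**Figure D1:**
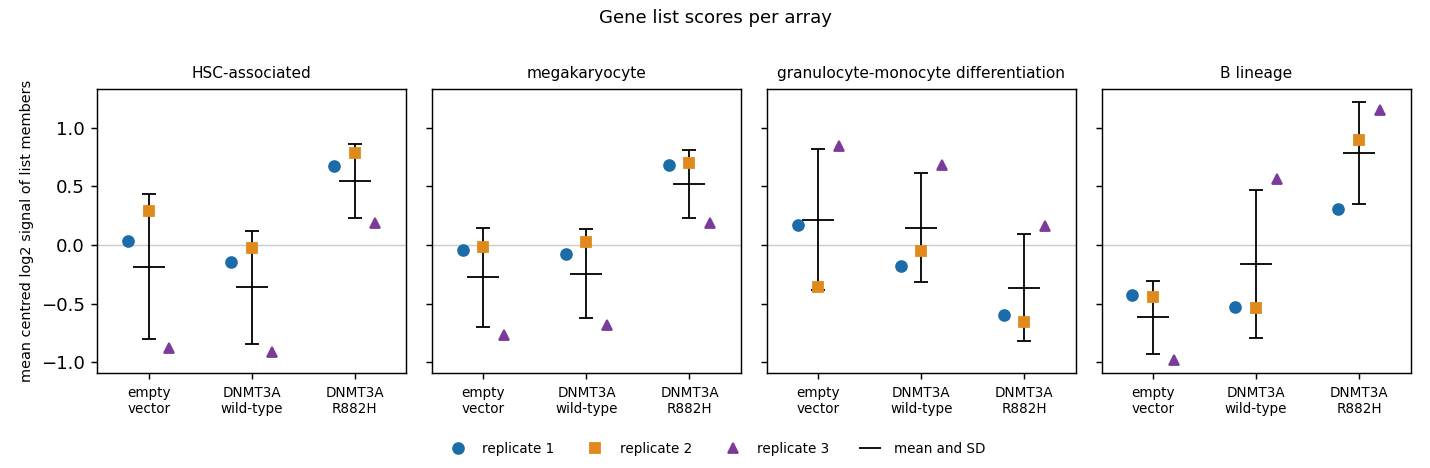
Scores of 4 gene lists on each of the 9 arrays, as the mean centred log2 signal of the list's members (vertical axis), by group (horizontal axis), with points for single arrays marked by replicate number and bars for the mean and SD of 3 arrays. The R882H means were 0.55 for the stem cell list and 0.52 for the megakaryocyte list against -0.18 and -0.28 with empty vector, and replicate 3 lay apart from the other 2 arrays of its group in the first 3 lists.

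The B lineage list had the largest median of any list in this comparison, 1.30 (2.47-fold), with 9 of 10 members higher and 6 of them past the threshold when adjusted over the list alone (adjusted p = 1.55e-05, and adjusted p = 0.306 with an estimated correlation). Vpreb1 and Vpreb2, which encode the surrogate light chain of the pre-B cell receptor, differed by 3.03 ± 0.94 and 2.25 ± 0.50 log2 units, and Blnk, an adaptor of that receptor, by 1.26 ± 0.42. Cd79a, a signalling chain of the B cell receptor, was at least 5.37-fold higher, since it was not well above background on any empty vector array. Ms4a1, Ebf1 and Igll1 of the same list were not well above background on all 3 arrays of any group and were not tested. Of the 10 tested members 3 were well above background on all 3 arrays of the R882H group alone and 5 on all 9 arrays. With those 5 the median was 0.25 and the list was not called (adjusted p = 0.0739), and with normexp background correction it was 0.46 with the call kept. Interferon response genes rose with a median of 0.50, 25 of 30 members being higher (adjusted p = 1.9e-05, and adjusted p = 0.396 with an estimated correlation). Gbp2 stood at 1.06 ± 0.27, Irf1 at 0.74 ± 0.27, Isg15 at 0.59 ± 0.22 and Irgm1 at 0.55 ± 0.22. Hox cluster genes and their cofactors, which pattern the embryo and sustain immature blood cells, rose with a median of 0.46 and 13 of 17 members higher (adjusted p = 0.00121, and adjusted p = 0.396 with an estimated correlation). Of these Hoxb2 stood at 3.08 ± 1.01, Hoxa5 at 1.22 ± 0.44 and Hoxb9 at 0.56 ± 0.15, and Hoxa2 was at least 2.35-fold higher. Hoxa9 and its cofactor Meis1 stood at 0.35 ± 0.65 and 0.88 ± 0.49. Imprinted genes, which are expressed from 1 parental copy under the control of DNA methylation, rose with a median of 0.28 and 17 of 19 members higher, 3 of them past the threshold when adjusted over the list alone (adjusted p = 0.00168, and adjusted p = 0.306 with an estimated correlation). Peg10, Dlk1, Magel2 and Mest differed by 1.39 ± 0.38, 1.26 ± 0.29, 0.77 ± 0.16 and 0.63 ± 0.30. Immediate early and heat shock genes rose with a median of 0.35 and 16 of 24 higher (adjusted p = 0.0389, and adjusted p = 0.457 with an estimated correlation). Egr1 stood at 1.08 ± 0.47, Dusp2 at 0.77 ± 0.33, Dusp1 at 0.60 ± 0.34 and Zfp36 at 0.47 ± 0.24.

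Growth and cell division genes fell by small amounts. Targets of Myc and genes of ribosome biogenesis had a median of -0.23, and 29 of 30 members were lower (adjusted p = 7.8e-05, and adjusted p = 0.457 with an estimated correlation). Nhp2 stood at -0.55 ± 0.23, Hspd1 at -0.39 ± 0.16, Dkc1 at -0.40 ± 0.18 and Ncl, for which 1 of 2 detected probes had the opposite sign, at -0.44 ± 0.19. DNA replication genes had a median of -0.20, and 27 of 32 members were lower (adjusted p = 0.00509, and adjusted p = 0.396 with an estimated correlation). The origin recognition gene Orc1 stood at -0.51 ± 0.15, the helicase subunit gene Mcm4 at -0.35 ± 0.13, Gins2 at -0.46 ± 0.18 and Chaf1a at -0.63 ± 0.31. Mitosis genes had a median of -0.18, and 23 of 29 members were lower (adjusted p = 0.0138, and adjusted p = 0.457 with an estimated correlation). Tpx2 stood at -0.56 ± 0.20, Aurkb at -0.46 ± 0.19, Ccnb1 at -0.38 ± 0.19 and Birc5 at -0.30 ± 0.17. In this comparison the median difference ran from 0.20 among the dimmest of 5 equal bins of genes to -0.13 among the brightest. After cyclic loess, an intensity-dependent normalization chosen after seeing the data, the DNA replication and mitosis lists were no longer called, at -0.11 (adjusted p = 0.0854) and -0.09 (adjusted p = 0.174). The Myc list was still called after it, at -0.12 (adjusted p = 0.00679), and lists matched on mean signal had a median of -0.12 before it. With quantile normalization the Myc median was -0.12 with the call kept, and the DNA replication (-0.12, adjusted p = 0.0700) and mitosis (-0.12, adjusted p = 0.0907) lists were not called. The mitosis list was not called without a filter on dim probes either (-0.17, adjusted p = 0.0509).

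Of 25 lists camera called 11 against empty vector, 7 higher and 4 lower, while fry and camera with an estimated correlation called 0. After cyclic loess the split was 8 higher and 2 lower. No single gene passed the adjusted threshold with limma, where 1201 genes had an unadjusted p under 0.05 (704 higher, 497 lower), against 656 by chance. The count of 1201 became 704 without R882H replicate 1 and 669 without R882H replicate 2, both near the chance count. It was 758 with slide as a block, 1805 with the replicate block and 2050 with array weights. The genes with the smallest p did not pass either, at an adjusted p of 0.314. Higher among them were the placental hormone gene Prl3b1 at 1.05 ± 0.17, the synaptic vesicle gene Syp at 0.89 ± 0.15 and Ier5 at 1.83 ± 0.33, with Olfr635 at least 1.35-fold and C1qtnf1 at least 1.43-fold higher. Lower were Ak4, a mitochondrial adenylate kinase, at -1.19 ± 0.20, Sptlc2 of sphingolipid synthesis at -0.76 ± 0.14 and Zbtb16, the zinc finger gene PLZF, at -0.75 ± 0.14, with Odf2l at least 1.64-fold and the endocytic adaptor Dab2 at least 3.28-fold lower. Of the fixed panel, Kit, Ly6a, Flt3, Bmi1, Ezh2 and Cdkn1a stood at 0.25, 0.12, 0.24, -0.13, 0.09 and 0.11, each with an SE of at least 0.21. For Bmi1, 1 of 2 probes had the opposite sign. When adjusted over the list alone, members passed in the B lineage, imprinted, megakaryocyte (2) and uncalled T and NK lineage (2) lists and in no other list of the 25.

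The other 14 lists were not called against empty vector. Medians were 0.36 for erythroid genes, -0.32 for mast cells, basophils and eosinophils, 0.26 for endothelial and stromal genes, 0.24 for sorting markers and self-renewal factors, 0.17 for T and NK lineage genes, 0.17 for germline genes silenced by methylation, and 0.14 for macrophages and dendritic cells. They were 0.11 for CDK inhibitors and quiescence regulators, 0.08 for Polycomb repressive complex 1, 0.05 for multipotent and lymphoid-primed progenitors, -0.03 for mature neutrophils, -0.08 for p53 targets and -0.14 for Polycomb repressive complex 2, beside the methylation machinery given above. Of the 5 sex-linked genes only 1 was measured, and this list was not tested. The 3 empty vector arrays lay on 1 slide that held no R882H array. A fit with slide as a block therefore reaches empty vector through wild-type replicate 1 alone. R882H replicate 3, alone on its slide, adds nothing to it. Number 3 thus enters that fit with empty vector and wild-type DNMT3A but not with R882H. The blocked medians therefore also carry the difference between replicate numbers. With slide as a block the stem cell median was 1.20, megakaryocyte 1.07, interferon 0.71, Hox 0.69, imprinted 0.61, mitosis -0.37, Myc targets -0.35 and granulocyte-monocyte -0.73, all still called. The B lineage (0.63, adjusted p = 0.0714), DNA replication (-0.13, adjusted p = 0.131) and immediate early (0.27, adjusted p = 0.131) lists were not, and the multipotent and lymphoid-primed list was, at 0.85 (adjusted p = 0.0135). Lists that ended without a single array were Hox genes (0.03, adjusted p = 0.112), interferon (0.26, adjusted p = 0.0518) and immediate early genes (0.21, adjusted p = 0.185) without empty vector replicate 3. Immediate early genes also ended without R882H replicate 3 (0.12, adjusted p = 0.259), and mitosis without empty vector replicate 1 (-0.06, adjusted p = 0.340). Medians that moved with the call kept were Hox genes without empty vector replicate 2 (0.72), imprinted genes without R882H replicate 2 (0.14) and immediate early genes without empty vector replicate 1 (0.21). Lists also called without 1 array were erythroid (0.84) and macrophage (0.28) genes, without empty vector replicate 1, and sorting markers (0.37) and CDK inhibitors (0.21), without empty vector replicate 2. Sorting markers were called after cyclic loess (0.25, adjusted p = 0.0321) and quantile normalization (0.26, adjusted p = 0.0327) too. So were CDK inhibitors with genes well above background on all 9 arrays (0.11, adjusted p = 0.0269) and erythroid genes with the array median (0.20, adjusted p = 0.0464). Immediate early genes were not called with array weights (0.21, adjusted p = 0.162) or with only the 2 groups compared in the fit (median unchanged at 0.35, adjusted p = 0.0692). With normexp background correction the megakaryocyte, Hox and imprinted medians were 0.43, 0.27 and 0.15 with the calls kept.

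The comparison of R882H with wild-type DNMT3A asks what the substitution adds to the expression of the enzyme itself. Its R882H arrays are those of the comparison above and its wild-type arrays those of the comparison below, so the results are not independent of either. A difference here can lie with the wild-type arrays. Aldh5a1 and Cdkn1a, for example, were also lower with wild-type DNMT3A than with empty vector, without passing. The stem cell list rose here too, with 26 of 27 members higher, a median of 0.77 (1.71-fold) and 3 members past the threshold when adjusted over the list alone (adjusted p = 1.76e-09, and adjusted p = 0.351 with an estimated correlation). Vwf, the blood clotting protein gene that marks platelet-biased stem cells, differed by 2.40 ± 0.60, Robo4 by 1.54 ± 0.34, Krt18 by 1.45 ± 0.22 and Gata2 by 0.77 ± 0.24. All 15 measured megakaryocyte genes were higher, with a median of 0.35, a mean of 0.77 and 2 members past the threshold when adjusted over the list alone (adjusted p = 4.38e-06, and adjusted p = 0.351 with an estimated correlation). Besides Vwf they included the platelet chemokine gene Pf4 at 2.00 ± 0.66 and the platelet surface genes Treml1 and Gp9 at 1.34 ± 0.44 and 1.21 ± 0.30. Erythroid genes rose with a median of 0.64 and 12 of 15 members higher (adjusted p = 0.00564, and adjusted p = 0.466 with an estimated correlation). The erythropoietin receptor gene Epor stood at 1.22 ± 0.45, the water channel gene Aqp1 at 1.20 ± 0.42 and Tspan33 at 1.26 ± 0.48, while Alas2, which encodes the first enzyme of haem synthesis in red cells, stood at -0.57 ± 0.28.

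The granulocyte-monocyte list fell with a median of -0.46 and 20 of 26 members lower (adjusted p = 0.00682, and adjusted p = 0.591 with an estimated correlation). The groups overlapped on its score, R882H replicate 3 at 0.17 lying above wild-type replicates 1 and 2 at -0.18 and -0.06. Irf8, which directs monocyte and dendritic cell fate, differed by -1.01 ± 0.32, Cebpa by -0.71 ± 0.35, Mpo by -0.92 ± 0.40 and Ctsg by -1.26 ± 0.62. Without wild-type replicate 3, the array with the highest granulocyte-monocyte score of its group, the median was -0.23 (adjusted p = 0.284), and without R882H replicate 1 or 2 it was -0.41 (adjusted p = 0.0549) or -0.35 (adjusted p = 0.0626), while without R882H replicate 3 it was -0.78. Macrophage and dendritic cell genes rose with a median of 0.21 and 9 of 14 members higher (adjusted p = 0.0332, and adjusted p = 0.357 with an estimated correlation). The members differed in direction: the antigen presentation genes H2-Ab1 and H2-Eb1 stood at 0.97 ± 0.28 and 0.60 ± 0.25, the iron exporter gene Slc40a1 at 1.54 ± 0.46 and the monocyte chemokine receptor gene Ccr2 at -1.51 ± 0.64. This call ended without wild-type replicate 1 or 2 (0.20, adjusted p = 0.101, and 0.14, adjusted p = 0.107) and without R882H replicate 1 or 3 (0.06, adjusted p = 0.129, and 0.28, adjusted p = 0.0636). Without R882H replicate 2 the median was 0.34 with the call kept. The list was not called without a filter on dim probes (0.19, adjusted p = 0.147) or with the replicate block (median unchanged at 0.21, adjusted p = 0.0904).

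B lineage genes rose with a median of 1.09 and 7 of 10 members higher (adjusted p = 0.00259, and adjusted p = 0.351 with an estimated correlation). Wild-type replicate 3 scored 0.56 on this list, above R882H replicate 1 at 0.30, while wild-type replicates 1 and 2 scored -0.52 and -0.53. Vpreb1 stood at 2.42 ± 0.94, Vpreb2 at 1.75 ± 0.50, Cd79a at 1.42 ± 0.50 and Vpreb3 at 1.21 ± 0.50. With the 5 members well above background on all 9 arrays the median was -0.04 and the list was not called (adjusted p = 0.453). Hox genes and cofactors rose with a median of 0.46 and 14 of 17 higher (adjusted p = 0.00259, and adjusted p = 0.357 with an estimated correlation). Hoxb2 stood at 3.12 ± 1.01, Hoxa2 at 1.71 ± 0.69 and the cofactor gene Pbx3 at 0.87 ± 0.38. Of the 17 members 3 were well above background on all 3 arrays of the R882H group alone, and without a filter on dim probes the list was not called (0.29, adjusted p = 0.0595). Immediate early and heat shock genes rose with a median of 0.42 and 19 of 24 higher (adjusted p = 0.000906, and adjusted p = 0.351 with an estimated correlation). Jun stood at 0.92 ± 0.29, Jund at 0.66 ± 0.17 and the chaperone genes Dnajb1 at 0.43 ± 0.15 and, lower, Hsp90aa1 at -0.36 ± 0.14. Interferon response genes rose with a median of 0.19 and 21 of 30 higher (adjusted p = 0.00682, and adjusted p = 0.525 with an estimated correlation). Irf7 stood at 0.96 ± 0.50, Oasl2 at 0.89 ± 0.40, Gbp2 at 0.70 ± 0.27 and Isg15 at 0.60 ± 0.22.

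Lists tied to growth and division fell, by small amounts. Mitosis genes had a median of -0.20 with 24 of 29 lower (adjusted p = 0.00515, and adjusted p = 0.525 with an estimated correlation). The cyclin gene Ccnb1 stood at -0.54 ± 0.19, Ndc80 at -0.51 ± 0.20, Aurkb at -0.44 ± 0.19 and Bub1 at -0.39 ± 0.14. Myc and ribosome biogenesis genes had a median of -0.19 with 25 of 30 lower (adjusted p = 0.00564, and adjusted p = 0.641 with an estimated correlation). Nolc1 stood at -0.64 ± 0.19, Mybbp1a at -0.40 ± 0.19, Hspd1 at -0.31 ± 0.16 and C1qbp at -0.28 ± 0.15. DNA replication genes had a median of -0.15 with 28 of 32 lower (adjusted p = 0.00817, and adjusted p = 0.351 with an estimated correlation). The flap endonuclease gene Fen1 stood at -0.56 ± 0.15, Orc1 and the ribonucleotide reductase gene Rrm2 at -0.43 ± 0.15 and -0.43 ± 0.23, and Mcm4 at -0.33 ± 0.13. Subunits of Polycomb repressive complex 2, which methylates histone H3, had a median of -0.17 with 10 of 11 lower (adjusted p = 0.0279, and adjusted p = 0.351 with an estimated correlation). Rbbp7 stood at -0.49 ± 0.17, the catalytic subunit gene Ezh2 at -0.42 ± 0.21, Eed at -0.23 ± 0.20 and Mtf2, for which 1 of 2 probes had the opposite sign, at -0.46 ± 0.19. After cyclic loess none of these 4 lists was called, with medians of -0.11 for mitosis (adjusted p = 0.0544), -0.12 for Myc (adjusted p = 0.0544), -0.09 for DNA replication (adjusted p = 0.0781) and -0.12 for Polycomb genes (adjusted p = 0.104). Nor was the macrophage list, at 0.16 (adjusted p = 0.0775). With quantile normalization the Polycomb list was not called (-0.15, adjusted p = 0.0818). With normexp background correction the stem cell, erythroid, B lineage, Hox and macrophage medians were 0.41, 0.34, 0.45, 0.24 and 0.09 with the calls kept.

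Several of these calls were lost without 1 array. Without wild-type replicate 3 the lists of mitosis (-0.13, adjusted p = 0.243), Myc targets (-0.09, adjusted p = 0.388), DNA replication (-0.10, adjusted p = 0.0832), interferon (0.11, adjusted p = 0.141) and immediate early genes (0.15, adjusted p = 0.137) were not called. The stem cell median without it was 0.49 (adjusted p = 8.61e-05). Without number 3 in any group the mitosis (-0.22, adjusted p = 0.0918), interferon (0.13, adjusted p = 0.129) and immediate early (0.08, adjusted p = 0.129) lists were not called, and endothelial and stromal genes were, at 0.73 (adjusted p = 0.0309). The Myc list also ended without R882H replicate 1 (-0.14, adjusted p = 0.0549) or 2 (-0.12, adjusted p = 0.0940), and its median was -0.29 without either wild-type replicate 2 or R882H replicate 3. The Polycomb list ended without wild-type replicate 1 or 2 or R882H replicate 3 (-0.16, adjusted p = 0.0993, -0.14, adjusted p = 0.150, and -0.25, adjusted p = 0.140), and the megakaryocyte median was 0.58 without wild-type replicate 1. Slide 2 held R882H replicates 1 and 2 and wild-type replicates 2 and 3. Number 3 stood there on the wild-type side alone, so medians within this slide also carry the difference between replicate numbers. Within it the stem cell median was 1.20 (adjusted p = 3.18e-12), megakaryocyte 0.54, erythroid 0.70, B lineage 0.51 and Hox 0.66. The others were immediate early 0.39, interferon 0.29, granulocyte-monocyte -0.79, mitosis -0.30, Myc targets -0.26 and DNA replication -0.18, all called. The macrophage (0.17, adjusted p = 0.111) and Polycomb (-0.20, adjusted p = 0.360) lists were not called there. Called there but not over all slides were imprinted genes, at 0.21 (adjusted p = 0.00954), multipotent and lymphoid-primed genes, at 0.39 (adjusted p = 0.0360), and T and NK lineage genes, at 0.10 (adjusted p = 0.0466). Slide as a block gave the same medians, and the multipotent and lymphoid-primed list was not called with it (adjusted p = 0.165).

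Camera called 13 of the 25 lists, 8 higher and 5 lower, and fry and camera with an estimated correlation called 0. After cyclic loess 7 were higher and 1 lower. No single gene passed with limma, where 1062 had an unadjusted p under 0.05 (470 higher, 592 lower), against 656 by chance, and 1595 with array weights. Ggt1, a gamma-glutamyltransferase gene, came closest with an adjusted p of 0.0951 and was at least 2.88-fold higher with R882H, since no wild-type array had it well above background. Next in p, and also not passing, were Aldh5a1 of GABA breakdown at 1.49 ± 0.20 (adjusted p = 0.193), Tom1l1 at 1.26 ± 0.19 and Klhdc1 at least 2.11-fold higher. On the lower side stood Ak4 at -1.42 ± 0.20, the chemokine gene Ccl6, 4.01-fold lower, Ankrd44 at -0.87 ± 0.15 and Zfp503 at -1.40 ± 0.24. The cell cycle inhibitor gene Cdkn1a stood at 1.03 ± 0.34, and the remaining panel genes Spi1, Gata1, Ly6a, Meis1, Bmi1, Dnmt3b, Dnmt1, Hoxa9, Dnmt3a, Kit and Flt3 at -0.47, 0.58, 0.69, 0.46, -0.36, -0.33, 0.21, 0.19, 0.17, 0.10 and 0.01. For Dnmt3b 2 of 3 probes, and for Flt3 1 of 2, had the opposite sign. The other 12 lists were not called, although 2 CDK inhibitor, 2 endothelial and stromal, 1 p53 target and 1 T and NK lineage gene passed when adjusted over the list alone. The nearest was the list of imprinted genes at 0.11 (adjusted p = 0.0551), which was called without wild-type replicate 2 (0.14, adjusted p = 0.0322) or R882H replicate 3 (0.16, adjusted p = 0.00703). It was called with normexp background correction (0.07, adjusted p = 0.0405), array weights (0.13, adjusted p = 0.0372) and the replicate block (median unchanged at 0.11, adjusted p = 0.0254) too.

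**Figure D2:**
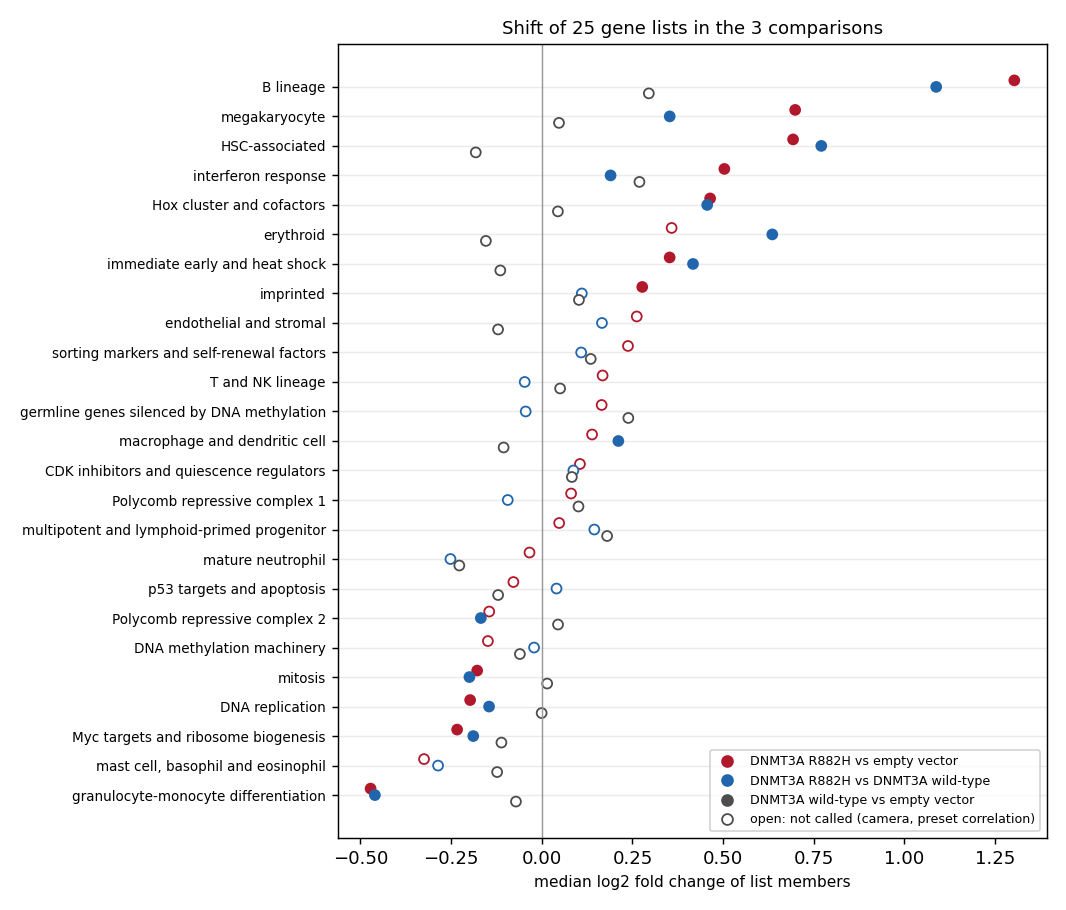
Median log2 fold change of list members (horizontal axis) for 25 gene lists (vertical axis, ordered by the comparison of R882H with empty vector) in 3 comparisons, with filled circles for lists called by camera with its preset correlation and open circles for the others. The comparisons with R882H have 11 and 13 filled circles and the comparison of wild-type DNMT3A with empty vector has 0; with an estimated correlation all 3 have 0.

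The comparison of wild-type DNMT3A with empty vector asks how cells transduced with the wild-type enzyme differ from cells with the vector alone. Stem cell genes lay at a median of -0.18, megakaryocyte genes at 0.05, granulocyte-monocyte genes at -0.07, B lineage genes at 0.30, interferon genes at 0.27, Hox genes at 0.04, erythroid genes at -0.15 and imprinted genes at 0.10. None of the 25 lists was called by camera, whose smallest adjusted p was 0.332. At an unadjusted p under 0.05 there were 2, the B lineage and interferon lists, and both fry and camera with an estimated correlation called 0. When adjusted over the list alone, 2 endothelial and stromal, 1 imprinted and 1 CDK inhibitor gene passed. Within slide 1, which held the 3 empty vector arrays and 1 wild-type array, the interferon median was 0.46, and slide as a block gave the same value. Both rest on that 1 wild-type array, which the fits assume to vary like the other arrays (adjusted p = 0.00832 and adjusted p = 0.00911). Without empty vector replicate 3 the stem cell and erythroid lists were called, at -0.53 (adjusted p = 0.000252) and -0.36 (adjusted p = 0.0280). Without empty vector replicate 2 the interferon, erythroid and Myc lists were called, at 0.37, -0.32 and -0.19 (adjusted p = 0.00377, adjusted p = 0.0355 and adjusted p = 0.0443). Without wild-type replicate 2 the B lineage, stem cell, immediate early and interferon lists were called, at 0.36, -0.24, -0.17 and 0.16 (adjusted p = 0.0326 for B lineage and adjusted p = 0.0389 for the others).

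No single gene passed in this comparison either with limma, where 780 had an unadjusted p under 0.05 (446 higher, 334 lower), against 656 by chance, and 1282 without wild-type replicate 3. The smallest p belonged to Aldh5a1, at -1.63 ± 0.20 log2 units, and to Olfr635, at least 1.43-fold higher, both with an adjusted p of 0.209. Others of small p that did not pass were the metalloprotease gene Adamdec1 at 1.62 ± 0.23, Lenep at 1.79 ± 0.26, Rabggta at 1.56 ± 0.26 and the protease inhibitor gene Timp1, at least 1.86-fold higher. Lower were Cyb561 at -1.89 ± 0.36, Apol11b at -0.94 ± 0.17, Klhdc1 at least 1.39-fold and the potassium channel gene Kcnj5 at least 5.33-fold. In the fixed panel Cdkn1a stood at -0.93 ± 0.34, Ly6a at -0.57 ± 0.39, Dnmt1 at -0.36 ± 0.15 and Ezh2 at 0.51 ± 0.21. Spi1, Mpo, Cebpa, Gata1, Meis1, Hoxa9, Flt3, Kit, Bmi1, Dnmt3b and Dnmt3a stood at -0.28, 0.02, 0.24, 0.57, 0.42, 0.16, 0.23, 0.15, 0.23, 0.38 and 0.18, where 2 of 3 Dnmt3b probes had the opposite sign.

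Log2 fold changes of the comparisons of R882H and of wild-type DNMT3A against the same empty vector arrays correlated across the tested genes at r = 0.456, where genes are not independent replicates. Groups with no change simulated against these shared arrays gave a mean r of 0.499 over 100 simulations, with a range of 0.475 to 0.532. The covariance was 0.0698 against a simulated mean of 0.0605, with a range of 0.0555 to 0.0655, a difference of 0.00923. These simulated groups had independent arrays. In a simulation chosen after seeing the data, same-numbered arrays were correlated by the mean of their observed correlations. It gave a mean r of 0.464, with a range of 0.424 to 0.509 that holds the observed r, and a mean covariance of 0.0447, with a range of 0.0396 to 0.0510, a difference of 0.0251. Both simulations drew genes independently, so their ranges leave out the spread that correlated genes add. They cannot decide whether the excess covariance is a shared change. With the empty vector arrays split between the comparisons, the covariance ran from -0.0355 to 0.0320 and r from -0.143 to 0.135.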

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

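The splits of the samples below and slide as a block were planned. The other tests in this part were chosen only after the results were seen. They are the gaps on slide 2, the scores at each replicate number, the lists matched on mean signal, cyclic loess and the probes without a symbol. Probes without a gene symbol stand outside the comparisons of genes, and 14209 of them were well above background on all arrays of at least 1 group. With limma 1 of these changed between R882H and empty vector and 8 between wild-type DNMT3A and empty vector, 5 higher and 3 lower. Between R882H and wild-type DNMT3A it was 0, with 873 at an unadjusted p under 0.05. Those counts were 1382 and 971 for the comparisons with empty vector, against 710 by chance. The probe that changed with R882H (A_30_P01032725) is placed on the reverse strand of mm9 chromosome 8, between 122920901 and 123008463. It was at least 1.70-fold higher, well above background on 3 R882H, 2 wild-type and 0 empty vector arrays. The limma adjusted p of 0.00314 belongs to a difference of 2.81 ± 0.19 (SE) log2 units that uses the dim empty vector values, not to this bound. The same probe is 1 of the 8 changed with wild-type DNMT3A (adjusted p = 0.0191), where its bound allows no fold above 1. Of the 8 changed with wild-type DNMT3A, a chromosome 17 probe between 3198868 and 3394643 was at least 3.54-fold higher. This probe and several others of the 8 were not well above background on any array of 1 group. Their p-values therefore rest on values near the floor. A chromosome 13 probe between 112337405 and 112356455 differed by -2.62 ± 0.28 log2 units. What these probes measure was not analysed here.

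The stem cell, megakaryocyte and granulocyte-monocyte lists shifted together in the R882H arrays, and slide or signal intensity could produce such a shift. Against wild-type DNMT3A the tables argue against slide, since on slide 2 the lowest R882H array lay 0.698 above the highest wild-type array on the stem cell score, with gaps of 0.659 and -0.544 for the other lists, on 2 arrays a group. Against empty vector slide and group cannot be told apart, because no slide held both and the blocked stem cell median of 1.20 reaches empty vector through 1 wild-type array. Lists matched on mean signal had a median of 0.02 against empty vector and 0.01 against wild-type DNMT3A, where the stem cell medians were 0.69 and 0.77. These values, and medians of 0.74 and 0.77 after cyclic loess with the calls kept, argue against intensity as the whole cause. The stem cell median lay at percentile 100 of the matched lists, which drew genes independently. That percentile is no measure of chance, since the uncalled sorting marker list also lay at 100 against empty vector. Each group held replicate numbers 1, 2 and 3. On the stem cell score R882H read 0.67, 0.78 and 0.19 in that order. Empty vector read 0.03, 0.29 and -0.88, and wild-type DNMT3A -0.15, -0.03 and -0.91. R882H lay highest at each number, also on the megakaryocyte score, and lowest on the granulocyte-monocyte score. Every number stood once in each group, so replicate number by itself cannot set the group means apart. These lists were picked for their shift in the same arrays. The scores, on 1 array a group at each number, are therefore no separate test. An effect of R882H, or of other differences between the samples, stays open as a hypothesis. Of the 27 stem cell genes 6 stand in another list too.

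Splitting the 6 arrays of a comparison into 3 and 3 gives 10 splits, too few for a share under 0.05. For lists, R882H against empty vector had 11 calls and the highest other split 14, with 3 of the 10 splits as large. R882H against wild-type DNMT3A had 13, the highest other split 10, and 1 of the 10 was as large. Wild-type DNMT3A against empty vector had 0, and all 10 reached that. The highest other had 12 and 2274 genes at an unadjusted p under 0.05 and set empty vector replicates 1 and 3 with wild-type replicate 3 against the rest, which points to a structure of the samples. Among splits parting all 3 same-numbered pairs of that comparison the others had 0, 4 and 2 lists. At an unadjusted p under 0.05 R882H against empty vector had 1201 genes and the split of empty vector replicates 1 and 3 with R882H replicate 3 had 1366 and 11 lists. R882H against wild-type DNMT3A had 1062 and the split of wild-type replicates 1 and 3 with R882H replicate 3 had 1131. For adjusted p the real splits had 0 genes, the highest others 0, 1 and 3, and all 10 splits reached the real count in each comparison.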

How the results depend on the processing

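Of 1775 list values under the alternatives, 119 were no longer past the threshold, 32 passed it and 7 reversed. Of the rest, 1557 counted as kept and 60 as moved. A called list was kept with its call and direction. An uncalled list was kept if its median moved by less than the spread between arrays within groups, whatever its sign. Of 3676 values of named genes 3424 moved by less than the spread and 252 by more. Testing every probe on its own called 1 probe for R882H against empty vector and 6 for wild-type DNMT3A against empty vector, all without a symbol. With an estimated correlation or fry, 0 lists were called in either R882H comparison. Cyclic loess left 8 lists for R882H against wild-type DNMT3A. With slide as a block, or on slide 1 alone, 1 list was called for wild-type DNMT3A against empty vector, and both rest on 1 wild-type array. Leaving out 1 array gave 7 to 13 lists for R882H against empty vector, 7 to 12 against wild-type DNMT3A and 0 to 4 between the other groups. Without number 3 in any group the lists numbered 8, 11 and 0. The correlation of fold changes was 0.737 with slide as a block, where both comparisons reach empty vector through wild-type replicate 1 and no unchanged value was simulated, 0.339 to 0.621 without 1 array and 0.00204 on average with the empty vector arrays split between the comparisons, where they are no longer shared.

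With the authors' value table and its columns as named, lists numbered 2, 4 and 2, the Dnmt3a difference was -0.35 and the correlation 0.598. Against empty vector R882H medians reversed to 0.12 for granulocyte-monocyte and -0.37 for multipotent and lymphoid-primed genes. Against wild-type DNMT3A they reversed to 0.34 for mast cell, 0.0911 for mitosis and 0.0625 for Myc genes, and between the other groups to -0.30 for interferon and -0.52 for multipotent genes. With columns given to the arrays whose values they hold, the lists numbered 11, 13 and 0, all 11 and 13 were shared, the Dnmt3a difference was 0.36, the correlation 0.456 and no list reversed, so the column names account for these. For the other changes the cause was not tested.

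Same-numbered arrays of R882H and empty vector correlated at 0.0885, 0.198 and 0.279 and of R882H and wild-type DNMT3A at 0.0713, 0.137 and 0.239, so with number 1 short of 0.1 the numbers were not taken to pair these samples, although 5 and 6 of the 6 arrays correlated best with their own number. With the replicate block the counts stayed at 0 genes in all comparisons and 11, 13 and 0 lists, of which 11 and 12 were shared. The macrophage list against wild-type DNMT3A was not called with it (adjusted p = 0.0904). Between 53.4% and 64.8% of probes were well above background, which limits what could be measured of the rest.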

Other observations

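The genes named in this part, the B cell gene sets outside the lists and the tests of the explanations were chosen only after the values were seen, while the tests of genes with limma and of the lists were planned. Cdkn2a, which encodes the cell cycle inhibitors p16 and ARF, was well above background on all 3 wild-type DNMT3A arrays and on 0 of the others. It was at least 2.07-fold lower with R882H than with wild-type DNMT3A, and at least 1.71-fold higher with wild-type DNMT3A than with empty vector. Between R882H and empty vector it has no bound, and it entered the tested genes through the wild-type group alone. It passed only when adjusted over the list alone, in the comparison of R882H with wild-type DNMT3A. Of the same list Cdkn2d stood at 0.50 ± 0.14 (SE) log2 units in R882H against wild-type DNMT3A, and Cdkn2c at 1.14 ± 0.26 in wild-type DNMT3A against empty vector. The T-bet gene Tbx21 stood at 0.86 ± 0.16 against empty vector and 0.88 ± 0.16 against wild-type DNMT3A, and Thy1, a surface marker of T cells and some progenitors, at -0.81 ± 0.21 against empty vector. The collagen gene Col1a2 stood at 1.35 ± 0.33 and Col3a1 at least 1.84-fold higher in R882H against wild-type DNMT3A, and Perp, a p53 target in cell death, at -1.70 ± 0.36. None of these passed over all genes with limma.

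The B lineage list had a higher mean score in R882H arrays, with wild-type replicate 3, at 0.56, above R882H replicate 1, at 0.30. B lineage cells in the sorted fraction may be a source, although the lineage gate would remove cells with mature surface markers. Early B genes outside the list had a median of 0.86 against empty vector (SE over 5 genes 0.613). Rag1 stood at 3.24, Il7r at 1.65, Dntt at 0.86, Rag2 at 0.41 and Cd24a at -0.35. Rag1 and Il7r were well above background on only 2 empty vector arrays, and Rag1 on only 2 wild-type arrays. Against wild-type DNMT3A these 5 genes, in the same order, stood at 2.19, 0.77, 0.37, -0.44 and -0.40. Mature B genes outside the list had a median of 0.42 against empty vector (SE over 8 genes 0.123), with 7 of 8 higher. The brightest of them, Cd37, stood at -0.22, and the highest, Ly6d at 0.93, was well above background on only 1 empty vector array. H2-Ab1 and H2-Eb1 of this set, at 0.56 and 0.71, also stand in the macrophage and dendritic cell list. The set is therefore not specific to B cells. Early or mature B cells and lymphoid-primed LSK progenitors, which also express early B genes, cannot be told apart with these values.

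Of the 9 columns in the authors' deposited values, 7 held the array of another sample. All 9 columns follow the order empty vector, R882H, wild-type by replicate, so a candidate explanation is that columns were written in group order under sample names in another order. Scanner output attached to the wrong samples stays open, since the Dnmt3a gap of -0.99 between the lowest transduced and the highest empty vector array decides nothing while the probe's place relative to the transgene is unknown. Beyond B lineage cells in the sorted fraction, no biological explanation was tested.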
